A study of Oryctolagus cuniculus with 2 samples.

How the data were processed

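Single-nucleus RNA-seq was analysed from the retinas of 10-month-old wild-type and CLRN1 knockout rabbits. Per the labels, a 5 mm punch was taken from each animal in the visual streak, 2 to 3 mm ventral of the myelinated nerve fibre band, and snap-frozen. Nuclei of 3 animals per genotype were mixed in equal concentration, with a target of 10000 nuclei, and captured as 1 droplet library per genotype with 10x Genomics chemistry that reads the 3' ends of polyadenylated transcripts. The labels state that nuclei were assigned to animals from natural genetic variation. That assignment was not used here, and each genotype was therefore treated as 1 library.

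The submitters' processing notes name Cell Ranger 7.0, Seurat 4.3.0, DESeq2 1.38.0 and the rabbit genome build OryCun2.0, without their roles. The filters on nuclei, the treatment of doublets and the removal of free RNA are not given in the sources used here. The lowest UMI count of a deposited nucleus was 499 and the highest mitochondrial share 14.1%. The deposited counts are raw UMI counts, as whole numbers per nucleus in the authors' table of nuclei and as a matrix of 15806 numbered rows and 6542 numbered columns. The mitochondrial value per nucleus is deposited as a percent of its UMIs, and in every nucleus it corresponded to a whole number of UMIs within a tolerance of 1e-06. The authors deposited 9 module scores per nucleus, each named for a cell type, with no gene list. Their column names have the form written by Seurat's module scoring, which subtracts the mean log-normalised level of control genes from that of a gene list. The authors' cluster numbers (26 clusters, 0 to 26 with 25 not used), cell types (7) and embedding coordinates were taken as deposited. The embedding and clusters were made by the authors from both libraries, and whether the libraries were integrated is not given in the sources used here.

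The matrix as analysed here carries numbers in place of names for genes and nuclei. Its column totals and numbers of detected genes equalled those of the table of nuclei at the same position for all 6542 columns, but columns were not assigned to libraries by position, and no gene was named by its place. The matrix was used only as a whole: it held 15149542 UMIs, of which 5.26% lay in 1 gene and 10.8% in the 10 highest genes, and 3 genes had no UMI. Analyses of genes that had been fixed before the data were examined were therefore not run. These were the edgeR, DESeq2 and limma comparisons per cell type and over all nuclei, the 53 gene lists (15 of cell type markers and 38 of pathways), the contrast of Müller glia with rods and the CLRN1 level, which would have checked the genotype labels. The rule for naming genes was also fixed then. It took the 10 genes with the smallest p in each direction in Müller glia and in rods, 3 in each direction in other cell types, up to 4 members of each list described and the genes of the Usher proteins. Without separate animals it took the 10 highest and 10 lowest genes by log2 ratio among those with enough UMIs, and with no gene names it named none.

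Nuclei were assigned to libraries by the library name in the authors' table. For each library, shares of nuclei per cell type and cluster were computed over all nuclei and over nuclei other than rods, with exact Clopper-Pearson intervals at 95%. Nuclei of a library are not replicates, so the intervals cover counting error only, and a difference is called beyond counting error where the intervals do not overlap. This rule is stricter than a direct comparison of the shares. Overlapping intervals therefore do not show that a difference lies within counting error. For UMIs per nucleus, the median is given with a 95% interval from order statistics. For module scores, medians, quartiles and differences of medians are given. Scores depend on depth, and differences were therefore also taken within 4 bins of UMIs per nucleus, divided at 1000, 2000 and 4000 UMIs. Bins with at least 10 nuclei of each library were used, weighted by the smaller number of nuclei. No doublet caller was run, since it needs genes or counts tied to nuclei.

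Alternatives fixed before the data were examined were shares over nuclei with 1000 or more UMIs, shares over nuclei other than rods, and depth in rods only. Alternatives chosen after seeing the data were shares over nuclei with 2000 or more UMIs or with under 1% mitochondrial UMIs, shares without cluster 14, without cluster 2, without clusters 9, 10 and 16, or without clusters 9, 10, 14, 16, 19 and 24, depth without these last 6 clusters, and the differences of scores within UMI bins and without the same 6 clusters. Cluster 16 was divided in the embedding by single linkage, joining nuclei up to 1 unit apart. A joining distance of 0.5 gave the same number of nuclei in the largest parts, 46 and 20, and at 2 the largest part held 77 of the 78 nuclei. Computations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.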

Results

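Nuclei were profiled from the retinas of wild-type rabbits and of rabbits with a knockout of CLRN1, all of them 10 months old. CLRN1 encodes clarin-1, a transmembrane protein whose loss in humans causes a form of Usher syndrome, in which both hearing and sight are lost. The tissue was a 5 mm punch from the visual streak, the horizontal band of high cell density in the rabbit retina. Nuclei of 3 animals per genotype were pooled into 1 droplet library, so the comparison set 1 wild-type library against 1 knockout library, and the animals were not analysed separately here. The wild-type library held 3484 nuclei with 6916018 unique molecular identifiers (UMIs, each standing for 1 captured transcript), and the knockout library held 3058 nuclei with 8233524 UMIs. With 1 library per genotype no test was made and no p-value is given. The intervals printed are exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only, and genotype, animal pool and library cannot be told apart. Where intervals overlap, a difference beyond counting error is not excluded.

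The comparison asked whether the cell populations of the retina differed between the wild-type and the knockout library, with Müller glia as the cell type the study placed first. The authors' annotation divided the nuclei into 26 clusters and 7 cell types. Rods, the photoreceptors of dim light, made up 64.2% of wild-type and 67.3% of knockout nuclei. Amacrine cells, inhibitory interneurons of the inner retina, were the next most frequent type, at 16.1% and 15.3%. The other 5 types each held under 6% of either library. In 23 of the 26 clusters the module score with the highest median, a score per nucleus for a set of cell type genes, was that of the cell type the authors had given the cluster.

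**Figure D1:**
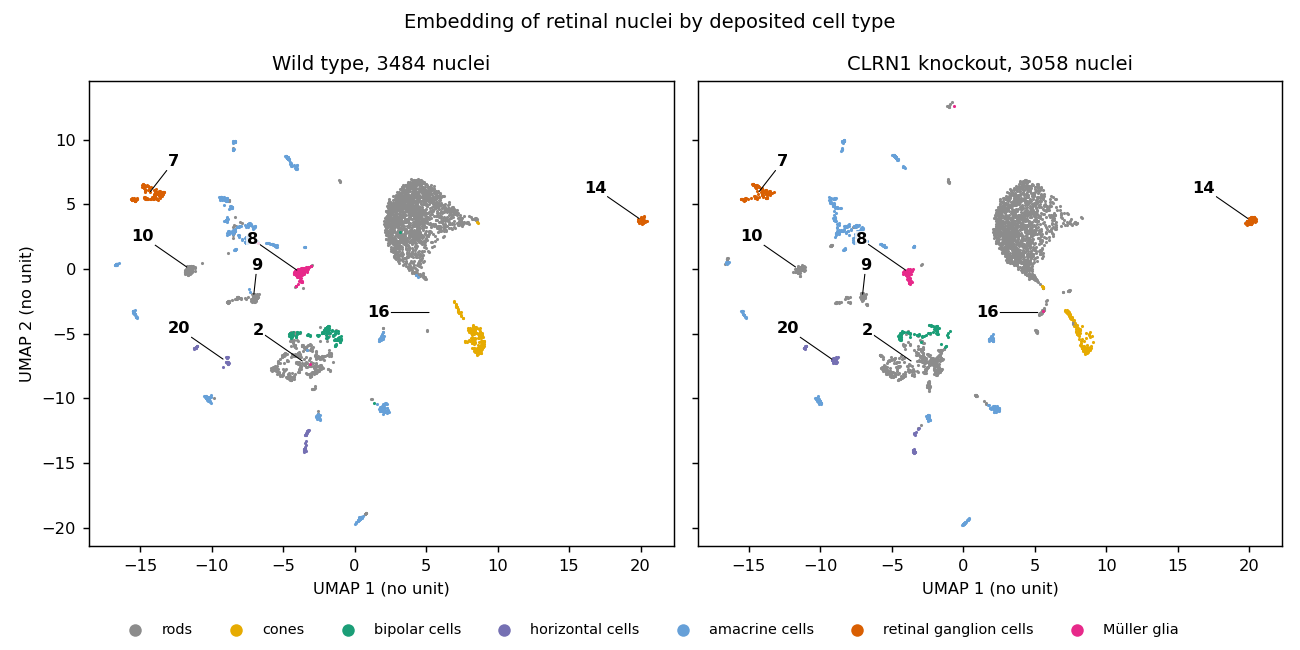
Position of each nucleus on both axes of the authors' UMAP embedding (no unit), for the wild-type library on the left and the knockout library on the right, coloured by the authors' cell type. Numbers mark clusters named in the text. Cluster 16 held 2 nuclei in the wild-type library and 76 in the knockout library, and cluster 14 held 26 and 81.

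Müller glia, the radial glial cells that span the retina and handle its potassium, water and glutamate, were the cell type with the largest relative difference in share. They made up 3.76% of wild-type nuclei (131 nuclei, interval 3.15 to 4.45%) and 1.77% of knockout nuclei (54 nuclei, 1.33 to 2.30%), a 2.13-fold lower share in the knockout library. Among nuclei other than rods the shares were 10.5% (8.86 to 12.3%) and 5.41% (4.09 to 6.99%). Bipolar cells, which carry the photoreceptor signal to the inner retina, were also less frequent in the knockout library, at 4.08% (3.44 to 4.79%) and 2.62% (2.08 to 3.25%). Both differences exceeded counting error over all nuclei, but among nuclei other than rods the intervals of bipolar cells overlapped, at 11.4% (9.68 to 13.3%) and 8.01% (6.40 to 9.87%). Relative to cones and to bipolar cells Müller glia were also less frequent in the knockout library, with intervals that overlapped, for cones only narrowly. They made up 41.9% (36.3 to 47.5%) of the wild-type and 30.5% (23.8 to 37.9%) of the knockout nuclei that were Müller glia or cones. With bipolar cells as the partner these shares were 48.0% (41.9 to 54.1%) and 40.3% (31.9 to 49.1%).

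The share of cones, the photoreceptors of bright light and colour, was 5.22% (4.51 to 6.02%) in the wild-type and 4.02% (3.35 to 4.78%) in the knockout library. Rods were at 64.2% (62.6 to 65.8%) and 67.3% (65.6 to 69.0%), and amacrine cells at 16.1% (14.9 to 17.3%) and 15.3% (14.1 to 16.7%). For these 3 types the intervals of the libraries overlapped over all nuclei. In none of the 11 amacrine clusters did the intervals of the libraries lie apart. The minimum of UMIs per nucleus, which were higher in the knockout library, changed these calls: among nuclei with 1000 or more UMIs the intervals lay apart for rods, at 44.3% and 54.9%, and for amacrine cells, at 26.8% and 22.7%. The rod intervals also lay apart under 1% mitochondrial UMIs, at 63.8% and 69.6%, and without cluster 14, at 64.7% and 69.2%, and among nuclei with 2000 or more UMIs the log2 ratio of knockout to wild-type share was 0.36 for rods and 0.40 for cones, against 0.07 and −0.38 over all nuclei.

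Rod nuclei were distributed differently over their 7 clusters. Cluster 0 held 26.6% (25.1 to 28.1%) of wild-type and 18.8% (17.5 to 20.3%) of knockout nuclei, whereas cluster 1 held 14.4% (13.3 to 15.6%) and 23.8% (22.3 to 25.3%). Clusters 0, 1 and 3 together, the main body of rods in the embedding, made up 47.3% and 46.9%. Cluster 2, which lay beside the bipolar cells in the embedding and had a median of 3968 UMIs per nucleus, against 663 in cluster 0 and 1027 in cluster 1, held 10.8% (9.78 to 11.9%) and 14.3% (13.1 to 15.6%). Cluster 16 was nearly absent from the wild-type library, with 0.0574% (0.00695 to 0.207%) against 2.49% (1.96 to 3.10%) in the knockout. Cluster 9 was 2.05-fold less frequent in the knockout, at 3.62% and 1.77%. The median rod score was 1.34 in cluster 0 and 1.41 in cluster 1 but −0.02 in cluster 9, 0.15 in cluster 10 and 0.04 in cluster 16, and these 3 clusters together held 6.13% of all nuclei.

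Retinal ganglion cells, the output neurons of the retina, made up 4.25% (3.60 to 4.97%) of wild-type and 5.76% (4.96 to 6.64%) of knockout nuclei. The intervals overlapped over all nuclei and were apart among nuclei other than rods, at 11.9% (10.1 to 13.8%) and 17.6% (15.3 to 20.1%). They were also apart without rod cluster 2, at 4.76% and 6.71%. The 2 ganglion cell clusters behaved differently. Cluster 7, with a median of 6458 UMIs per nucleus, held 3.50% and 3.11%, with overlapping intervals. Cluster 14, with a median of 704 UMIs and of 4.58% mitochondrial UMIs, held 0.746% (0.488 to 1.09%) and 2.65% (2.11 to 3.28%), and without it the log2 ratio of ganglion cell shares was −0.14 in place of 0.44. Horizontal cells, the interneurons that link photoreceptors laterally, were at 2.41% (1.93 to 2.98%) and 3.17% (2.58 to 3.86%). Cluster 20, the horizontal cluster with the highest horizontal cell score (median 1.61), was 2.28-fold more frequent in the knockout library, at 0.660% (0.419 to 0.989%) and 1.50% (1.10 to 2.00%). The median horizontal score of the remaining horizontal clusters, 19 and 24, was 0.20 and 0.19, and the intervals of their shares overlapped.

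**Figure D2:**
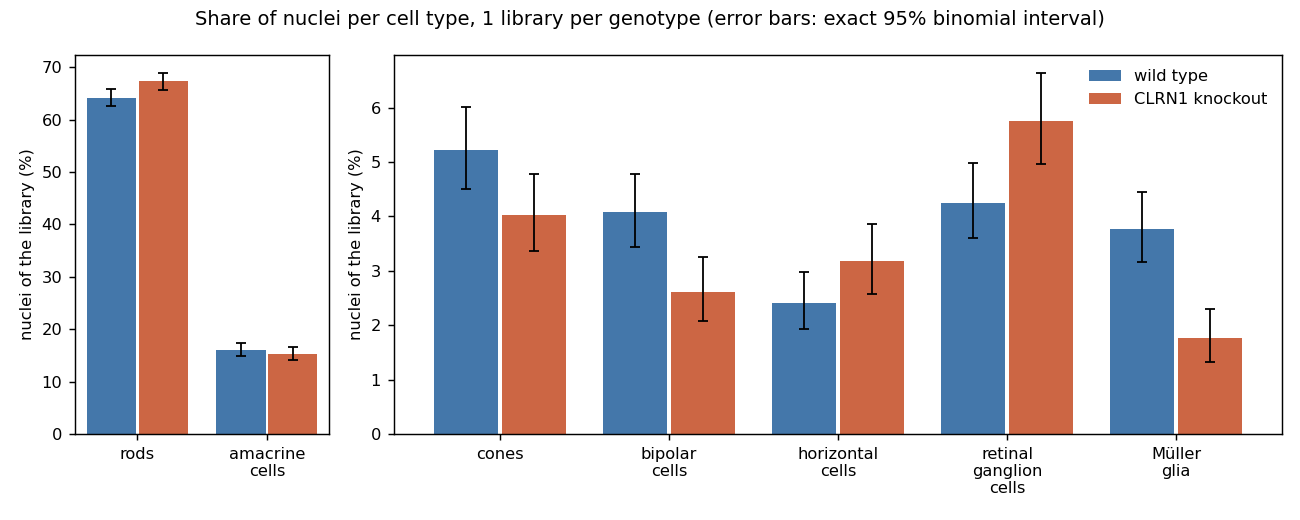
Percentage of the nuclei of each library (y axis) in each of the 7 deposited cell types (x axis), for wild type in blue and the CLRN1 knockout in orange, with exact 95% binomial intervals as error bars. The intervals of Müller glia (3.15 to 4.45% and 1.33 to 2.30%) and of bipolar cells (3.44 to 4.79% and 2.08 to 3.25%) lie apart.

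**Figure D3:**
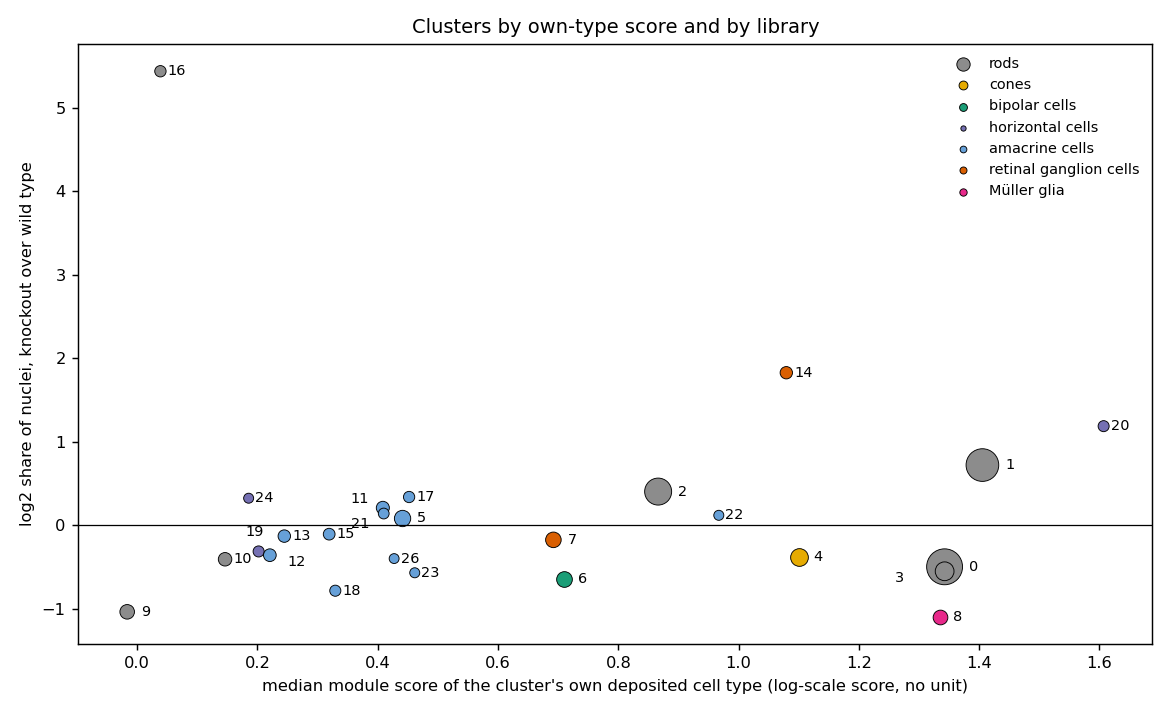
Each circle is 1 of 26 clusters, placed by the median module score of its own deposited cell type (x axis, no unit) and by the log2 ratio of its knockout to wild-type share of nuclei (y axis), with circle area growing with the number of nuclei. Cluster 16 stands apart at a log2 ratio of 5.44 and a rod score of 0.04, followed by ganglion cell cluster 14 at 1.83.

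Within the cell types, rods of the knockout library had the higher rod score. Its median was 1.11 (quartiles 0.67 and 1.54) in wild-type and 1.26 (0.89 and 1.67) in knockout rods. The difference of 0.15 was 0.26 when nuclei were compared within 4 bins of UMIs per nucleus, and the knockout median was the higher one in 4 of 4 bins. In rod cluster 2 the medians were 0.69 and 1.00. Outside rods, the median rod score was lower in knockout bipolar, horizontal, amacrine and Müller glia nuclei, by differences of −0.05 to −0.26, and higher in cones (0.36) and ganglion cells (0.34). Within each ganglion cell cluster it was lower in the knockout, at −0.47 and −0.58 in cluster 7 and 0.89 and 0.53 in cluster 14. Cluster 14, with the higher rod score, held 26 of 148 wild-type and 81 of 176 knockout ganglion cells. Within UMI bins the weighted difference of the rod score was negative in 5 of these 6 types. It ranged from −0.01 in bipolar cells to −0.17 in horizontal cells and in Müller glia, and was 0.02 in cones. In bipolar cells and in cones the knockout median was higher in 1 of the 2 bins and lower in the other. Müller glia had a median Müller glia score of 1.39 (0.67 and 1.81) in the wild-type and 1.24 (0.50 and 1.79) in the knockout library, a difference of −0.15. Within UMI bins the difference was −0.18, with the knockout median lower in 2 of 2 bins, and over all Müller glia the 95% intervals of the medians overlapped, at 1.17 to 1.61 and 0.94 to 1.52. Differences of the own score in cones, bipolar cells and amacrine cells were 0.01, 0.04 and 0.10, and within UMI bins 0.20, 0.05 and 0.06. In cones the knockout median was higher in 1 of the 2 bins and lower in the other. The ganglion cell score differed by 0.21 over all ganglion cells and by 0.05 without cluster 14. The horizontal cell score differed by 0.19, and by −0.09 within UMI bins. High-scoring cluster 20 held 23 of 84 wild-type and 46 of 97 knockout horizontal nuclei, and within it the score differed by −0.05. The genes behind the scores were not used here, and since the scores are on a log scale no folds are given.

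Nuclei of the knockout library carried more UMIs. The median was 1175.5 per wild-type nucleus (interval of the median 1130 to 1216) and 1552.5 per knockout nucleus (1462 to 1644), a 1.32-fold difference. The median was higher in the knockout library in 6 of the 7 cell types, from 869 against 1067 in rods to 2281.5 against 3729 in horizontal cells. Ganglion cells were the exception, at 5415 and 4772, although in ganglion cell cluster 7 the medians were 5924 and 7830. Mitochondrial transcripts, which mark cytoplasm carried over into a nuclear preparation, made up 0.287% of wild-type and 0.338% of knockout UMIs. The share of nuclei with over 1% mitochondrial UMIs was 7.41% (6.56 to 8.33%) and 8.18% (7.23 to 9.20%) over all types. Among ganglion cells it was 27.0% (20.1 to 34.9%) and 48.3% (40.7 to 55.9%), but in ganglion cell cluster 7 it was 13.1% and 12.6%, with overlapping intervals. Amacrine cells had more such nuclei in the knockout library, at 3.39% (2.06 to 5.25%) and 8.53% (6.16 to 11.4%), and rods fewer, at 7.96% (6.87 to 9.16%) and 5.15% (4.23 to 6.19%).

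**Figure D4:**
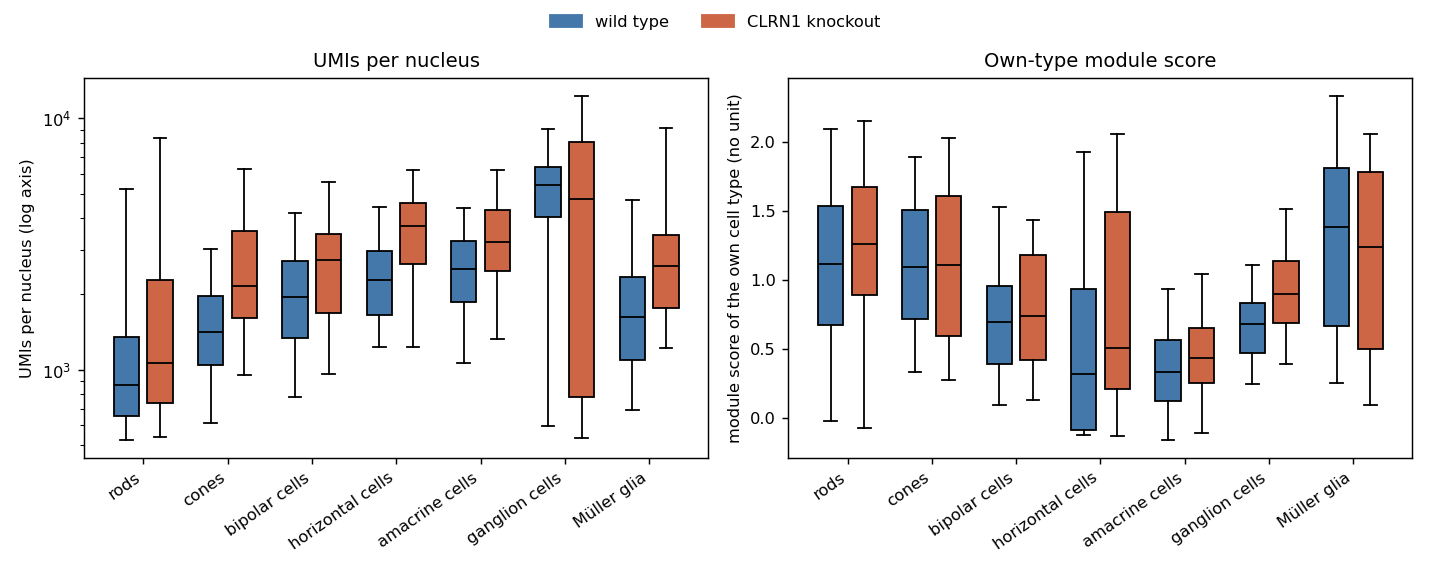
UMIs per nucleus on a log axis (left) and the module score of the own cell type (right, no unit) for each deposited cell type, with wild type in blue and the knockout in orange. Boxes span the quartiles with the median as a line and whiskers reach the 5th and 95th percentiles of nuclei, which are not replicates; knockout medians of UMIs lie above wild-type medians in every type except retinal ganglion cells.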

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

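The tests in this part were chosen only after the results were seen.

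Clusters that the authors called rods differed between the libraries in opposite directions, each beyond counting error. The log2 ratio of knockout to wild-type share was −0.50 in cluster 0, −0.55 in cluster 3 and −1.03 in cluster 9, against 0.72 in cluster 1, 0.41 in cluster 2 and 5.44 in cluster 16. The difference between these clusters was not tested, because each library gives 1 value per cluster. Some of these clusters also differed in depth or mitochondrial share. Clusters 0 and 1 had similar rod scores but medians of 663 and 1027 UMIs. Cluster 3 had a median of 0.97% mitochondrial UMIs, against 0.12% in cluster 0 and 0.06% in cluster 1. Knockout rods had more UMIs than wild-type rods, and fewer of them exceeded 1% mitochondrial UMIs. Whether this accounts for the differences in share was not tested.

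Cluster 16 held 2 wild-type and 76 knockout nuclei. The values argue against rods like those of clusters 0 to 3: 23.1% of its nuclei (interval 14.3 to 34.0%) had a rod score above the lower quartile of cluster 2. This share was 94.4% in clusters 0, 1 and 3 and, by construction of the limit, 74.9% in cluster 2. Depth was not matched, with medians of 2303.5 UMIs in cluster 16, 798 in clusters 0, 1 and 3 and 3968 in cluster 2. Clusters 9 and 10, also deposited as rods, were as low as cluster 16, at 36 of 180 nuclei (14.4 to 26.6%) and 19.6% (13.4 to 27.0%). Their rod label rests on the same annotation. The rod score was the highest median score in cluster 10 (0.15) but not in cluster 9 (−0.02). These clusters therefore cannot decide, and rods with a low score stayed open. Microglia also stayed open for the cluster as a whole, with 16.7% of its nuclei (13 of 78, 9.18 to 26.8%) above a microglia score of 0.1 against 0.480% of other nuclei, but its parts in the embedding differed: 55% (31.5 to 76.9%) of a part of 20 nuclei passed this score, and 0 of a part of 46 nuclei (0 to 7.71%). The part of 20 nuclei, 18 of them from the knockout library, may therefore hold microglia, although its highest median score was that of Müller glia, 0.26 against 0.21 for microglia. The part of 46, all from the knockout library, was not named by any of the 9 scores, its highest median being 0.10 for ganglion cells. A further part of 11 nuclei, all from the knockout library, held 1 nucleus above the microglia limit. Its highest median was 0.18 for ganglion cells. The last part was 1 knockout nucleus above that limit, with a microglia score of 0.57 and a rod score of 1.21. With 1 library per genotype, a cell population of the knockout retina, a single animal and a feature of that library remain open, untested explanations.

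Microglia, the resident immune cells of the retina, have a score but are not among the 7 cell types analysed here. A microglia score above 0.1, a threshold chosen after seeing the data, was found in 1.08% of knockout nuclei (33 nuclei, 0.744 to 1.51%) and 0.316% of wild-type nuclei (11 nuclei, 0.158 to 0.564%). Outside cluster 16 the shares were 0.704% (0.436 to 1.07%) and 0.287% (0.138 to 0.528%), with overlapping intervals.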

How the results depend on the processing

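The alternatives below were chosen after seeing the data, except shares over nuclei with 1000 or more UMIs, shares over nuclei other than rods, and depth in rods only. The lower shares of Müller glia and bipolar cells kept their direction in 8 of 8 alternatives, with log2 ratios of −1.09 to −0.79 and −0.79 to −0.51. Leaving out rods or the named clusters removed no nucleus of either type and changed only the denominator. This could hardly turn the direction, and only the limits on UMIs and mitochondrial share removed such nuclei. Over nuclei with 2000 or more UMIs the intervals overlapped for both, at 4.93% and 2.85% and at 6.19% and 4.13%, and for bipolar cells also among nuclei other than rods. The higher share of ganglion cells turned: its log2 ratio of 0.44 was −0.079 with 1000 or more UMIs, −0.54 with 2000 or more, −0.045 under 1% mitochondrial UMIs, −0.14 without cluster 14 and −0.14 without clusters 9, 10, 14, 16, 19 and 24, each of which removes most or all of cluster 14 by construction. Ganglion cell intervals lay apart with 2000 or more UMIs, at 10.9% and 7.51%. The limit removed more wild-type nuclei but few of cluster 7 (lower quartile 5317 UMIs), which alone lowers the ratio. With the same 6 clusters left out, the ratio of horizontal cells was 1.22 in place of 0.40, since cluster 20 alone then stood for the type. Thresholds of UMIs moved rods from 0.07 to 0.31 at 1000 and 0.36 at 2000, and cones from −0.38 to 0.40 at 2000. These limits removed a larger part of the wild-type than of the knockout nuclei of both types. Under 1000 UMIs lay 60.4% of wild-type and 45.9% of knockout rods, and the median cone had 1412 and 2144 UMIs. Other causes were not tested. The rod intervals lay apart in 5 of 7 alternatives. Amacrine intervals overlapped in 7 of 8, from −0.23 to 0.06, and lay apart with 1000 or more UMIs, at −0.24. The log2 ratio of median UMIs was 0.40, 0.30 in rods only and 0.40 without the 6 clusters. The higher rod score moved from 0.15 to 0.26 within UMI bins, the cone score from 0.01 to 0.20, the amacrine score from 0.10 to 0.06, the horizontal score from 0.19 to −0.09 and the ganglion cell score from 0.21 to 0.06. Settings fixed beforehand for genes, gene lists, CLRN1 and single animals, among them other normalisations, filters, tools, thinning and leaving out each animal, were not run, because gene names and the assignment of nuclei to animals were not used here. No paired analysis was possible with 1 library per genotype. Cell types with few nuclei, such as the 54 knockout Müller glia, limit what a share can show.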

Other observations

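The tests in this part were chosen only after the results were seen.

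Amacrine cells made up many small clusters. The 11 amacrine clusters had median amacrine scores from 0.22 in cluster 12 to 0.97 in cluster 22, and in 9 of them this was the highest median score. In cluster 12 the horizontal cell score was the highest, and in cluster 15 the rod score. Of single nuclei, the own score was the highest of the 9 in 85.5% of ganglion cells and 83.8% of rods, but in 65.0% of amacrine cells, 59.1% of horizontal cells and 54.1% of bipolar cells. The rod score was the highest in 34.4% of cones, 27.5% of bipolar cells, 24.3% of Müller glia and 9.26% of ganglion cells.

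The lower share of Müller glia nuclei in the knockout library was set against 3 explanations. Dilution by more rods and by cluster 14 would leave their share of the remaining nuclei alike, yet it was 5.88% (4.45 to 7.61%) in the knockout and 10.7% (9.05 to 12.6%) in the wild type. Placement in other clusters would need there the 1.63 percentage points of nuclei above the lower quartile of the Müller glia score that cluster 8 lacked. The knockout excess was 0.361 points, at most 1.12 from the outer bounds of both intervals. This excess lay in cluster 14, which held 16 such knockout nuclei and 1 wild-type nucleus. Outside clusters 8 and 14 such nuclei made up 0.785% (0.503 to 1.17%) of the knockout and 0.918% (0.629 to 1.29%) of the wild-type library. The 1.63 points carry counting error too, coming from 2.87% (2.34 to 3.48%) of wild-type and 1.24% (0.881 to 1.70%) of knockout nuclei, so this comparison cannot decide. Over all clusters such nuclei made up 3.82% (3.21 to 4.51%) of the wild-type and 2.55% (2.02 to 3.17%) of the knockout library, intervals that lie barely apart. Müller glia nuclei with a lower score were not counted, so their placement elsewhere stays open. A difference in pooling, dissociation or capture instead of genotype cannot be told apart from a loss of Müller glia with 1 library per genotype. The overlap of the intervals in the pairings with bipolar cells and, narrowly, with cones leaves open that these 3 types were captured less well together.

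The larger number of ganglion cell nuclei in the knockout library lay in cluster 14. More ganglion cells outside it were not seen: cluster 7 held 3.11% (2.52 to 3.78%) of knockout and 3.50% (2.92 to 4.17%) of wild-type nuclei. These intervals overlap and leave a moderate difference in either direction open. Low-RNA droplets that hold RNA of several cell types are a candidate explanation: the median of cluster 14 was 704 UMIs against 6458 in cluster 7, and its median rod score of 0.61 and Müller glia score of 0.45 lay above the 95th percentiles of cluster 7, 0.21 and 0.21. The cone score lay just above as well, at −0.096 and −0.106, but the bipolar (−0.13 and 0.04), horizontal (−0.07 and 0.31), amacrine (−0.09 and 0.08) and general photoreceptor scores (−0.31 and −0.28) lay below. These clusters were not matched for depth. Rods of cluster 0, at a median of 663 UMIs, had cone, horizontal and amacrine scores of −0.093, −0.045 and −0.071, near those of cluster 14. The scores therefore cannot decide, which leaves this explanation open. The ganglion cell score of cluster 14 had a median of 1.08 against 0.69 in cluster 7, but no nucleus of cluster 7 had under 1000 UMIs, so depth could not be matched. Damaged ganglion cells with free RNA of other cells remain possible and were not tested.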
